A study of Mus musculus with 52 samples.

How the data were processed

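The series measured RNA in gastrocnemius muscle of aged male C57BL/6 mice (22 to 24 months) by total RNA sequencing. The 52 libraries came from 52 samples in 13 groups of 4. AMB_W stands for ambulatory mice on plain drinking water. HU stands for hindlimb unloading, RL7 and RL14 for unloading followed by 7 or 14 d of reloading, and the last letters give the drink: W for water, M for metformin, L for leucine and ML for both. Libraries are named by their group and the replicate number of their title, so that HU_W 2 is replicate 2 of the unloaded water group.

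The deposited table holds raw counts per Ensembl gene, with whole numbers and no normalization, for 55487 genes and 1 column per library. The submitters' processing notes name the GRCm38 build and the tools STAR 2.7.3a, featureCounts 1.6.3 and DESeq2 1.30.0. Per the labels, libraries were stranded and ribosomal RNA was removed. The strand setting of the counting and the gene annotation release were not given in the sources used here, so genes that overlap another gene on the opposite strand are reported as uncertain. Symbols, positions and gene types were taken from GENCODE vM21 on GRCm38 by matching identifiers; 55141 of 55487 identifiers matched, and 107 symbols were held by more than 1 gene. Totals ran from 15605044 counts in HU_L 2 to 32492548 counts in HU_ML 4.

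Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, which left 16668. Libraries were scaled with TMM factors, and 1 robust quasi-likelihood model with a mean for each of the 13 groups was fitted to all 52 libraries, which left 39 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 16668 genes of a comparison, and an adjusted p under 0.05 counted as changed. Fold changes are given on the log2 scale with a standard error (SE) taken from the F statistic of the test, and levels as mean CPM (counts scaled by the library total and its TMM factor) with the SD between libraries (n = 4 per group). The median SE of a log2 fold change lay between 0.225 and 0.231 in the 19 comparisons, and the common dispersion was 0.045. Intervals and errors cover the spread between the libraries as deposited, and each library was taken as 1 mouse.

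The 19 comparisons set the water groups against AMB_W, RL7_W against HU_W, each treated group against the water group of its time, and ML against M and against L at each time. A test of 6 interaction terms asked whether treatment effects differed between the 3 times. 32 gene lists (cell type markers, matrix, fibre types, energy metabolism, protein turnover, inflammation, clock and stress genes), the rule for named genes, the comparisons and the first set of alternatives were fixed before the data were examined. Lists were tested with cameraPR of limma 3.58.1 on signed statistics of edgeR with an inter-gene correlation preset to 0.01, adjusted over the 32 lists of a comparison, and again with a correlation estimated per list. Counts of changed members are given over all genes tested and adjusted over the list alone.

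Named genes came from a rule. In the 3 comparisons with AMB_W, in RL7_W against HU_W and in the 3 comparisons of ML with water, it took the 6 highest and 6 lowest log2 fold changes among changed genes. These genes had an average log2 CPM of at least 1, no overlap between the libraries of both groups and no predicted or clone name. The other comparisons took 2 and 2. From each list, the 2 rising and the 2 falling changed members with the smallest p were added, and a set of genes of satellite cells, matrix and atrophy (Pax7 and Col1a1 among them) could be given in any comparison. Genes outside this rule are said to be chosen after their values were seen. For lack of room the text leaves out some genes that the rule names, not always from the end of a ranking, and 3 others are not reported here.

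The steps were tested on simulated data. Counts were drawn with each gene's mean level and spread over all libraries, and 200 genes with an average log2 CPM of at least 1 were changed in HU_W or in RL14_ML. In HU_W against AMB_W, 34.3% of genes changed by 1.5-fold, 83.6% of those changed by 2-fold and 97% of those changed by 4-fold were recovered. In RL14_ML against RL14_W these shares were 26.9%, 82.1% and 100%. Calls outside the changed genes and the shifted list numbered 5 of 154 and 2 of 146. The 1 list shifted by 1.5-fold was called in both, and 0 other lists were. Genes were drawn independently of one another, while the estimated correlation within the glycolysis list was 0.613 in the data. The simulation therefore cannot show the error rate of list or gene calls where genes move together or a library stands apart. All 78 pairs of replicates were compared for duplicated libraries; the lowest chi-square per degree of freedom between the counts of a pair was 6.82.

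Alternatives comprised RLE size factors, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, a fit of only the groups compared, a block by replicate number, each library left out in turn and, for lists, the estimated correlation. Added after the data were seen were a covariate for 5.8S rRNA (log2 CPM of n-R5-8s1), a fit without 12 libraries with liver transcripts (Alb above 16 CPM), and a fit without RL14_ML 1 and RL14_ML 6. For each comparison, the 8 libraries were also split into 4 and 4 in all 35 ways. No library and 0 columns of the table were left out of the values given first.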

Results

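The 52 libraries fall into 13 groups of 4 mice: ambulatory controls on water, and 4 drinks (water, metformin, leucine, both) at 3 times (unloading, and 7 or 14 d of reloading). Metformin is a diabetes drug that acts on energy metabolism, and leucine is an amino acid that stimulates protein synthesis. In hindlimb unloading, the hind legs bear no weight and the muscle wastes; reloading returns the weight. Totals ran from 15605044 to 32492548 counts per library, and groups of 4 gave a median SE of a log2 fold change near 0.23.

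Some libraries stood apart in liver transcripts, ribosomal RNA or small RNA. Alb, a liver transcript, exceeded 16 CPM in 12 libraries: HU_W 1 and 2, HU_L 5, HU_ML 4 and 6, RL7_M 1 and 2, RL7_L 2 and 5, RL14_W 5, and RL14_L 4 and 5. It reached 814.5 CPM in RL14_L 5 and stayed at or below 9.848 CPM in the other 40. A 5.8S ribosomal RNA gene (n-R5-8s1), which removal of ribosomal RNA should deplete, averaged 11.3 ± 3.37 CPM (SD, n = 4) in AMB_W and 4.99 ± 2.22 CPM in RL7_W. It averaged 0.718 ± 0.299 CPM in RL14_W, against 18.4 ± 5 CPM in RL14_M, 19.1 ± 7.47 CPM in RL14_L and 24.4 ± 8.9 CPM in RL14_ML. RL14_ML 1 held 7026 CPM of the small RNA gene Gm23935, which stayed at or below 189.4 CPM elsewhere, and in RL14_ML 6 the mitochondrial genes took 29.23% of counts. RL7_M 4 had a mean log2 CPM of 6.30 over the adipocyte markers, against 2.80, 2.99 and 2.30 in RL7_M 1, 2 and 3. The group mean with RL7_M 4 was 3.60 ± 1.82 (SD, n = 4).

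**Figure D1:**
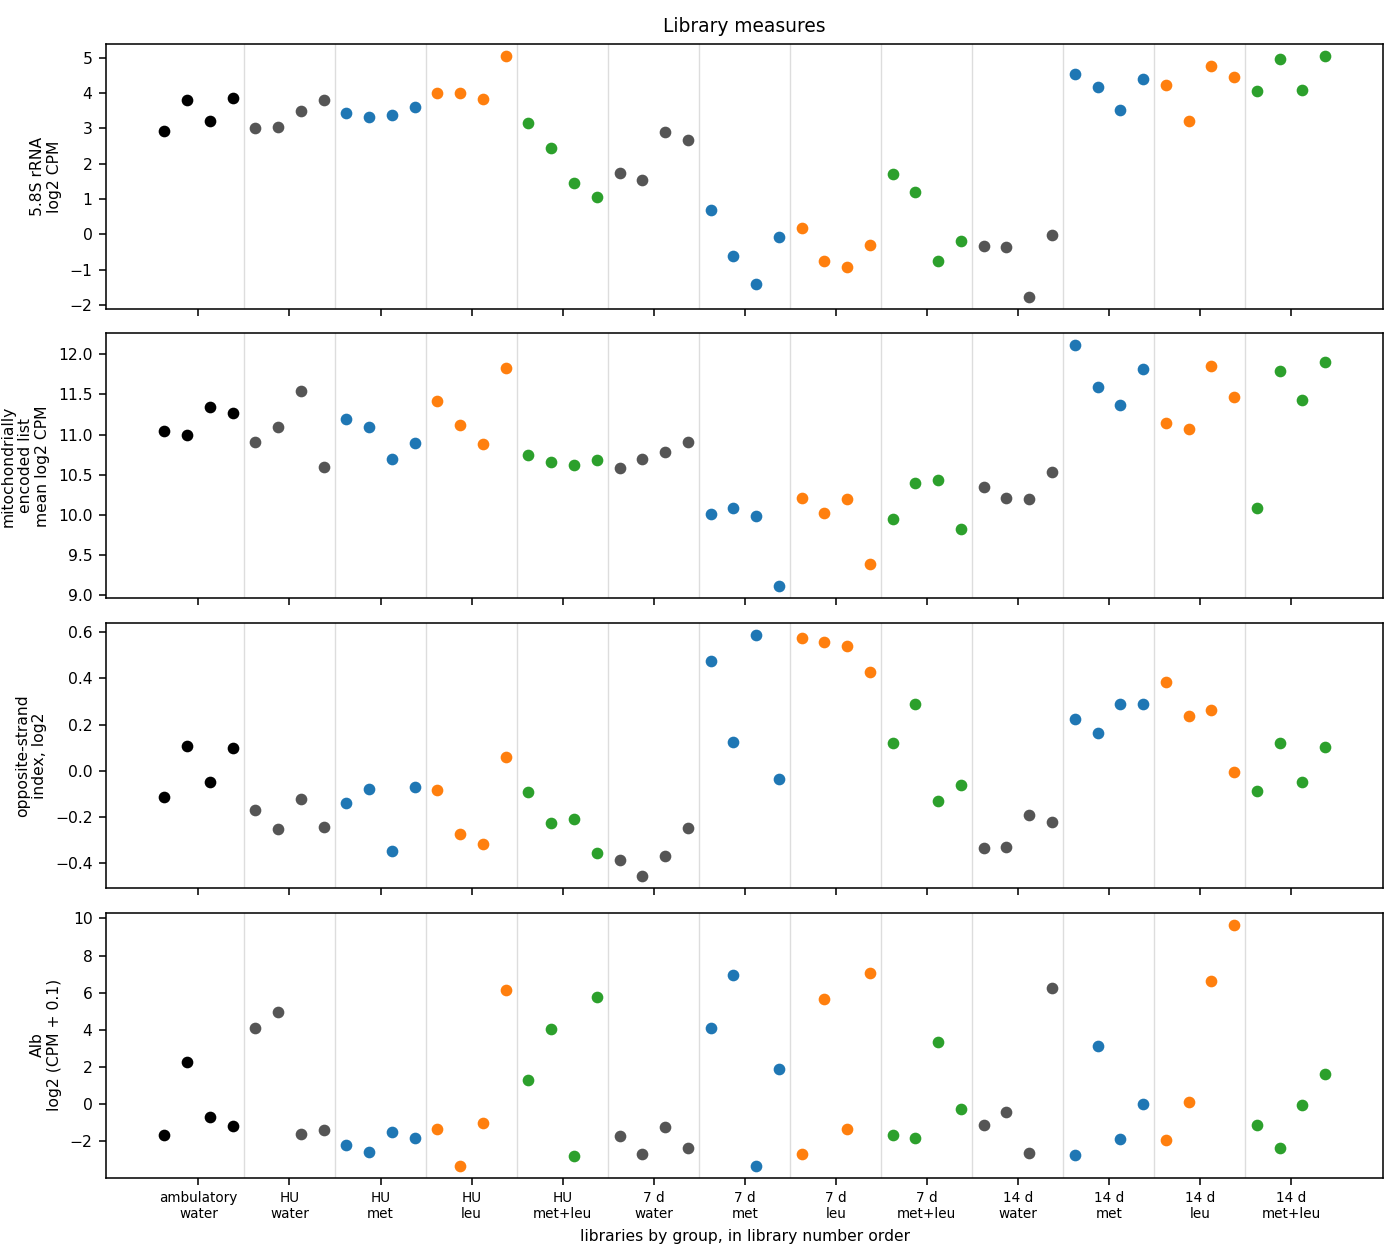
Each point is 1 of the 52 libraries in library number order, coloured by drink; the panels give the log2 CPM of 5.8S rRNA, the mean log2 CPM of the mitochondrially encoded list, the opposite-strand index (the mean log2 CPM of 58 genes that lie mostly opposite to an abundant gene, centred on all libraries) and the log2 of Alb CPM plus 0.1. At 14 d of reloading, 5.8S rRNA averaged 0.718 CPM with water and 18.4, 19.1 and 24.4 CPM with metformin, leucine and both.

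What unloading did to aged muscle was asked with HU_W against AMB_W. Ddit4, an inhibitor of mTORC1 signalling, rose 31.2-fold, from 2.02 ± 0.711 to 62.6 ± 26.8 CPM (SD, n = 4; log2 fold change 4.96 ± 0.52 SE, edgeR adjusted p = 2.06e-08). Foxo1, a transcription factor of muscle wasting, rose 4.38-fold, from 37.2 ± 2.84 to 163 ± 32.3 CPM (adjusted p = 2.79e-09). Trim63, the muscle ubiquitin ligase MuRF1, rose 1.84-fold (adjusted p = 0.0473, and from 0.0723 to 0.173 without any 1 of the 8 libraries). The other well-known ligase, Fbxo32, had a log2 fold change of 0.08 ± 0.23 (adjusted p = 0.921). Col1a1, the main chain of type I collagen, fell from 51.5 ± 12 to 11.6 ± 4.13 CPM, a 4.45-fold drop (adjusted p = 0.0253). Ddit4 (ENSMUSG00000020108) lies on chromosome 10 at 59949669 to 59951834, Foxo1 (ENSMUSG00000044167) on chromosome 3 at 52268336 to 52353221, and Col1a1 (ENSMUSG00000001506) on chromosome 11 at 94936224 to 94953042 of GRCm38.

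Among lists, the immediate early genes, which respond within minutes to stimulation, rose together: 6 of 12 rose over all genes tested and 11 adjusted over the list alone, and 0 fell (adjusted p = 9.31e-12, and 0.00529 with an estimated correlation). Fosb rose 20-fold from 0.3 CPM (log2 fold change 4.32, and 3.48 without HU_W 1 and 5.04 without AMB_W 3) and Jun 1.87-fold to 163 ± 15.7 CPM; Fos rose 10.4-fold. Of 6 red blood cell transcripts 5 rose, and 6 adjusted over the list alone (adjusted p = 4.14e-10, and 0.0106 with an estimated correlation), with Alas2, the first enzyme of haem synthesis, 10-fold and the globin gene Hbb-bs 9.73-fold higher. Of 22 fibrillar collagens and other matrix proteins 7 fell and 15 did not pass; 10 fell adjusted over the list alone (adjusted p = 4.24e-07, but adjusted p = 0.457 with an estimated correlation), with Col1a2 3.01-fold and Col3a1 3.14-fold lower. Of 20 genes of ubiquitin ligases, FoxO factors and the proteasome 5 rose and 15 did not pass; adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.00668, adjusted p = 0.378 with an estimated correlation). Eif4ebp1, a repressor of translation that sits in this list, rose 1.83-fold.

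Some further lists passed with the preset correlation alone. Of 15 macrophage markers 1 rose, Lyve1, by 2.5-fold, and 1 adjusted over the list alone (adjusted p = 0.0447, adjusted p = 0.85 with an estimated correlation). Of 12 cell cycle inhibitors and cytokines 1 rose, Nfkbia, an inhibitor of NF-kappa-B, by 1.97-fold, and 2 did adjusted over the list alone (adjusted p = 0.0447, adjusted p = 0.378 with an estimated correlation). Interferon-stimulated genes (0 of 13, 1 adjusted over the list alone) and ribosomal proteins (0 of 21, 0 adjusted over the list alone) had the same adjusted p of 0.0447, and of 0.85 with an estimated correlation. These 4 lists also missed the threshold with RLE factors or with 5.8S rRNA as a covariate. Leaving out AMB_W 2, AMB_W 5, HU_W 1 or HU_W 4 ended the call of each of these 4 lists, as did AMB_W 3 for the first 3 named and AMB_W 4 for ribosomal proteins, with adjusted p up to 0.176, 0.138, 0.267 and 0.22 in the order given. Of 17 genes of branched-chain amino acid breakdown 0 changed, with 1 lower adjusted over the list alone (adjusted p = 0.00486, adjusted p = 0.434 with an estimated correlation, and 0.069 without HU_W 4).

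Among the most changed genes outside these lists, Cebpd, a transcription factor of the acute phase, rose 6.7-fold. Lower were Aplnr, the apelin receptor, 3.52-fold, Gamt, which makes creatine, 2.87-fold, and the mitotic kinase Aurka 2.63-fold. In all, 464 of 16668 genes changed, 325 up and 139 down. The count was 305 without AMB_W 2, 304 without AMB_W 3, 255 without AMB_W 5, 290 without HU_W 2 and 123 without the 12 liver-transcript libraries, 2 of which are HU_W libraries. Col1a1 no longer passed without AMB_W 4, HU_W 2 or HU_W 4 (highest adjusted p = 0.108), Col3a1 without any library but AMB_W 3 and HU_W 1 (0.122), Col1a2 and Gamt without HU_W 2 (0.066 and 0.0625), Aplnr without AMB_W 4 or HU_W 3 (0.0809) and Lyve1 without AMB_W 2, AMB_W 3 or HU_W 1 (0.0561).

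The return of load was followed with RL7_W against HU_W. This comparison and HU_W against AMB_W share the HU_W libraries with opposite sign, so opposite directions in the 2 are expected in part without any change. Ddit4 fell 22.5-fold to 2.77 ± 0.775 CPM (log2 fold change -4.49 ± 0.50 SE, n = 4, edgeR adjusted p = 8.97e-08), and Foxo1 fell 5.47-fold to 29.7 ± 5.95 CPM (adjusted p = 8.28e-11). Arrdc2 fell 7.7-fold, Slc25a25, a mitochondrial carrier, 7.18-fold, and Ppp1r3c, which directs glycogen synthesis, 5.22-fold from 752 ± 96.7 to 144 ± 18 CPM. Trim63 fell 2.01-fold to 136 ± 24.5 CPM (adjusted p = 0.0133, and 0.0769 without RL7_W 2). Aplnr rose 6.22-fold, Kdr, a receptor for VEGF, 2.35-fold to 48.8 ± 12.6 CPM, and Egfl7, secreted by endothelium, 2.06-fold. Cish, a feedback inhibitor of cytokine signalling, rose 8.27-fold from 1.61 ± 1.16 to 13.3 ± 4.27 CPM (adjusted p = 0.0131, and 0.0719 without HU_W 2). Ppp1r3c (ENSMUSG00000067279) lies on chromosome 19 at 36731731 to 36736653 and Kdr (ENSMUSG00000062960) on chromosome 5 at 75932827 to 75978458.

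Lists of respiratory, matrix, basement membrane and endothelial genes rose with the preset correlation, and these 4 did not pass with an estimated correlation. Of 20 nuclear-encoded respiratory chain subunits 2 rose, Sdhc and Cyc1, and 10 adjusted over the list alone (adjusted p = 5.61e-06, adjusted p = 0.494 with an estimated correlation). Of 22 fibrillar collagens and matrix proteins 2 rose and 9 adjusted over the list alone (adjusted p = 0.000469, adjusted p = 0.562 with an estimated correlation), Col15a1 by 2.62-fold. Col1a1 had a log2 fold change of 1.54 ± 0.56 and an adjusted p of 0.101. Of 13 basement membrane genes 3 rose and 7 adjusted over the list alone (adjusted p = 0.00173, adjusted p = 0.494 with an estimated correlation), among them Col4a1 (1.81-fold) and Col4a2 (1.75-fold), the chains of type IV collagen. Of 11 endothelial markers 2 rose and 5 adjusted over the list alone (adjusted p = 0.000519, adjusted p = 0.427 with an estimated correlation). The single-gene calls ended for Col15a1 without RL7_W 1 (adjusted p = 0.0566) and for Col4a2 without HU_W 2 or RL7_W 2 (highest 0.117). Those for Col4a1, Sdhc and Cyc1 ended without any of 5 or 6 libraries, HU_W 2, 3 and 4 and RL7_W 1 and 2 for each and RL7_W 4 for Sdhc (highest 0.172, 0.188 and 0.219).

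Lists of protein breakdown, red blood cell and immediate early genes fell in RL7_W against HU_W. Of 20 ligase, FoxO and proteasome genes 4 fell and 5 adjusted over the list alone (adjusted p = 0.000519, adjusted p = 0.407 with an estimated correlation). Foxo3 fell 1.61-fold to 33.8 ± 2.58 CPM. Of 6 red blood cell transcripts 3 fell and 4 adjusted over the list alone (adjusted p = 0.000683), and of 12 immediate early genes 3 fell and 3 adjusted over the list alone (adjusted p = 0.00173), with Jun 2.1-fold lower; both had an adjusted p = 0.427 with an estimated correlation. In all 813 genes changed, 329 up and 484 down. The count was 410 without HU_W 2, 525 without HU_W 3, 473 without RL7_W 1 and 408 without RL7_W 2. It was 248 (67 up, 181 down) without the 12 liver-transcript libraries and 471 with 5.8S rRNA as a covariate.

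Whether muscle differed from ambulatory muscle after 7 d was asked with RL7_W against AMB_W. Trim63 had 136 ± 24.5 CPM against 149 ± 18.9 CPM (log2 fold change -0.12 ± 0.25 SE, n = 4, edgeR adjusted p = 0.901). Col1a1 had 33.8 ± 20.5 CPM against 51.5 ± 12 CPM (-0.61 ± 0.54, adjusted p = 0.755). With edgeR 0 genes changed, 1341 had an unadjusted p under 0.05 (833 would by chance), DESeq2 called 20 and voom with quality weights 156. Lists of 15 macrophage markers (mean log2 fold change 0.80, adjusted p = 1.82e-06, adjusted p = 0.375 with an estimated correlation) and 13 interferon-stimulated genes (0.99, adjusted p = 1.82e-06, adjusted p = 0.288 with an estimated correlation) were higher, with 0 members changed over all genes; adjusted over the list alone, 0 and 6 rose. The 11 endothelial markers (0.35, 1 rose adjusted over the list alone) and 20 nuclear-encoded respiratory chain subunits (0.24, 0 rose adjusted over the list alone) were higher, with an adjusted p = 1.06e-05 and 6.25e-05 (adjusted p = 0.275 and 0.509 with an estimated correlation), the second with a mean of 0.155 without RL7_W 2. The 11 mitochondrially encoded subunits were lower (-0.43, 0 adjusted over the list alone, adjusted p = 0.000187, adjusted p = 0.407 with an estimated correlation), and 5.8S rRNA was at 4.99 CPM against 11.3 CPM.

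After 14 d, RL14_W against AMB_W gave 29 changed genes, 20 up and 9 down, by edgeR. Eif4ebp1 was 1.94-fold higher at 19.9 ± 2.61 CPM (log2 fold change 0.95 ± 0.21 SE, n = 4, adjusted p = 0.0442), and Atf4, the transcription factor of the amino acid response, 1.5-fold higher at 62.6 ± 5.47 CPM (adjusted p = 0.0442). Cldn5, a tight junction protein of endothelium, rose 2.29-fold to 3.63 ± 0.795 CPM, Gstp2, which conjugates glutathione, 2.04-fold, and the small RNA genes Rpph1 and Scarna10 3.93-fold and 2.84-fold. Prkaa1, the alpha 1 subunit of AMP-activated kinase, fell 1.34-fold to 15.9 ± 1.37 CPM (adjusted p = 0.0442), the mitochondrial ribosomal RNA mt-Rnr1 2.76-fold and the 5.8S rRNA gene n-R5-8s1 15.3-fold. Of single genes, Col1a1 had a log2 fold change of -0.17 ± 0.53 (adjusted p = 0.895) and Pax7, the satellite cell transcription factor, 0.20 ± 0.27 (adjusted p = 0.724).

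Of 14 genes of glycolysis and glycogen use 0 changed over all genes but 12 rose adjusted over the list alone (mean log2 fold change 0.44, adjusted p = 2.37e-08, adjusted p = 0.508 with an estimated correlation). The 11 mitochondrially encoded subunits had a mean of -0.86, with 10 lower adjusted over the list alone (adjusted p = 3.4e-09, adjusted p = 0.508 with an estimated correlation). Of 13 basement membrane genes and 12 satellite cell markers, 4 each rose adjusted over the list alone and 0 over all genes (mean 0.35 and 0.30, adjusted p = 0.00893 and 0.022, adjusted p = 0.698 for both with an estimated correlation). The first was lost without AMB_W 3 or RL14_W 1 (highest 0.0756). With 5.8S rRNA as a covariate these 4 lists no longer passed and 0 genes changed. Of the genes named here, n-R5-8s1 passed without each library in turn, and each other changed gene missed the threshold without any of 6 to 8 of them (highest adjusted p = 0.222). The count of 29 moved with single libraries, to 2 without AMB_W 2, 3 or 5, 1 without AMB_W 4, RL14_W 1 or RL14_W 4, 3 without RL14_W 3 and 69 without RL14_W 5. It was 1409 without RL14_ML 1 and 6, which take no part in the comparison but in the shared estimate of spread; DESeq2 called 288 and 2990 genes had an unadjusted p under 0.05.

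**Figure D2:**
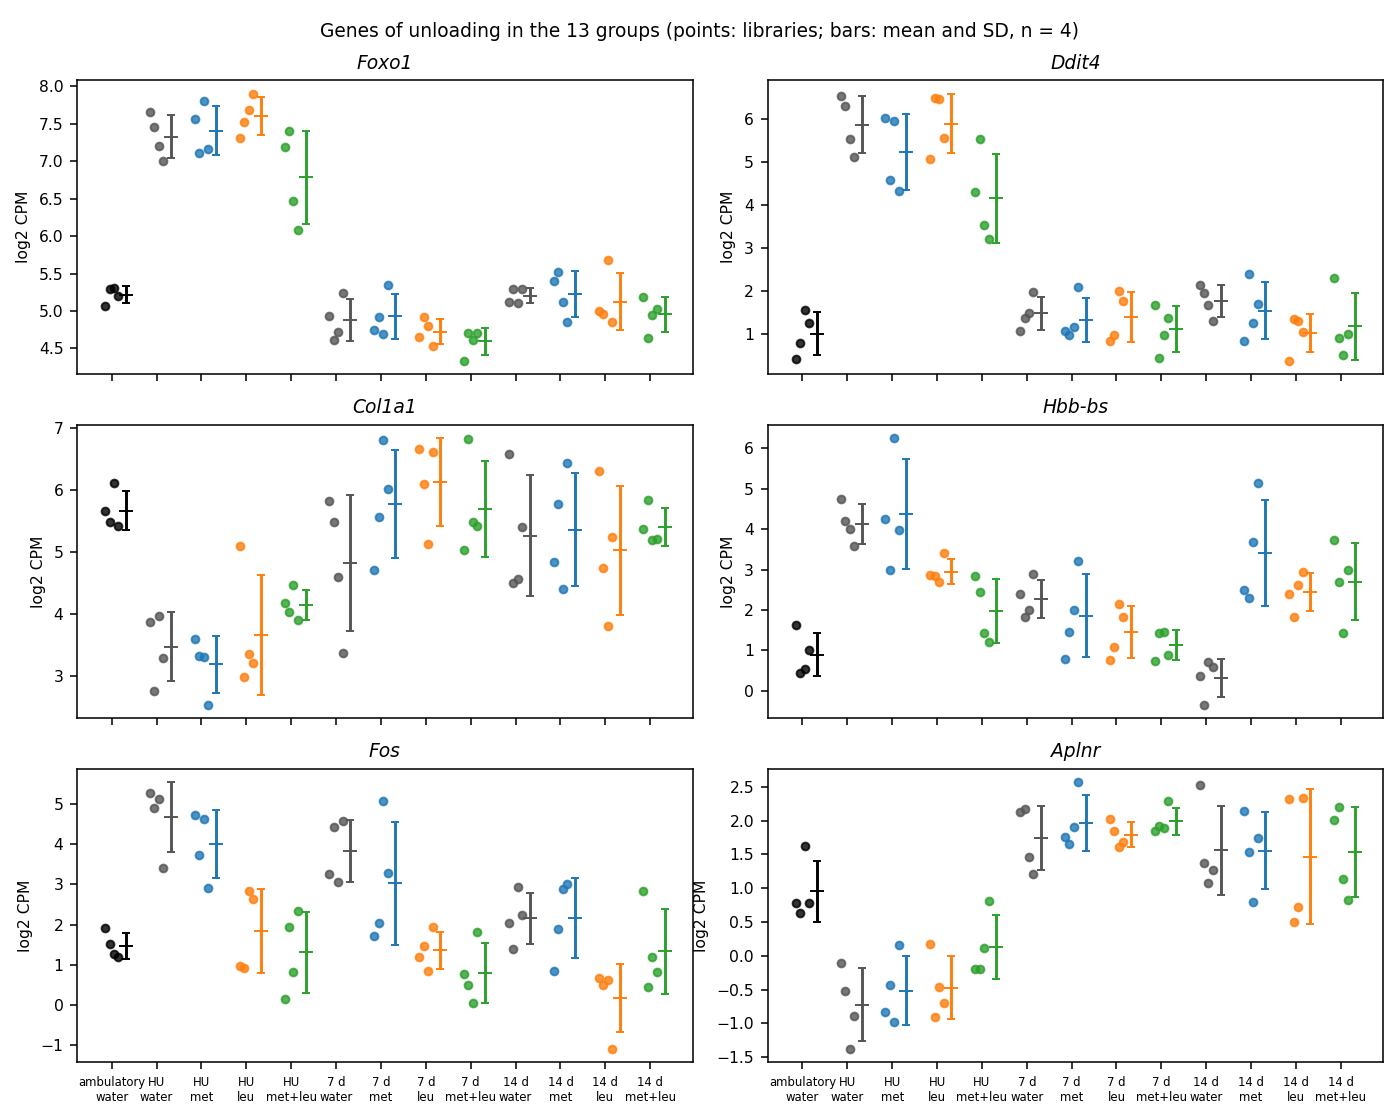
Log2 CPM of 6 genes in the 13 groups; points are libraries, and bars give the mean and SD (n = 4 per group). Ddit4 averaged 62.6 CPM in the unloaded water group against 2.02 CPM in the ambulatory group and 2.77 CPM after 7 d of reloading, and Col1a1 11.6 CPM against 51.5 and 33.8 CPM.

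What each drink added during unloading was asked against HU_W. With metformin (HU_M), Pax7 stood at 1.07 ± 0.406 CPM against 1.66 ± 0.252 CPM (log2 fold change -0.62 ± 0.30 SE, n = 4, edgeR adjusted p = 0.999) and Trim63 had a log2 fold change of 0.61 ± 0.25 (adjusted p = 0.999). With edgeR 0 genes changed, 647 had an unadjusted p under 0.05, DESeq2 called 16 and voom 0; 1 gene was called without HU_M 1, HU_M 2 or HU_M 4. Slow-twitch fibre genes (12 tested, mean log2 fold change -0.86, adjusted p = 0.00829), nuclear-encoded respiratory chain subunits (20, -0.14, adjusted p = 0.00383) and glycolysis genes (14, -0.17, adjusted p = 0.00317) were lower as lists, with 0 members changed over all genes and 0 adjusted over the list alone. With an estimated correlation each had an adjusted p = 0.862, and each was lost with voom, the last 2 also without the 12 liver-transcript libraries. Each also ended without HU_M 4, the fibre list without HU_W 3 or HU_M 3, the respiratory list without HU_W 1 or HU_M 3 and the glycolysis list without HU_W 1 (highest adjusted p = 0.351, 0.49 and 0.174). Without HU_M 1 the fibre and respiratory lists had means of -1.46 and -0.231.

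With leucine during unloading (HU_L), red blood cell and immediate early transcripts were lower. The 6 red blood cell transcripts had a mean log2 fold change of -2.12 ± 0.72 (SD over genes), with 0 changed over all genes and 6 lower adjusted over the list alone (adjusted p = 5.06e-12, and 0.00465 with an estimated correlation). Of 12 immediate early genes 1 fell and 5 adjusted over the list alone (adjusted p = 3.5e-11, and 0.00465 with an estimated correlation). Fosb, a stimulus-induced partner of Jun (ENSMUSG00000003545, chromosome 7 at 19302696 to 19310051), was the 1 gene that changed, 23.2-fold lower at 0.269 ± 0.225 CPM against 6.24 ± 5.71 CPM in HU_W (adjusted p = 0.0142), and its call ended without HU_W 1 or HU_L 1, 2 or 3 (highest adjusted p = 0.179); its log2 fold change was -4.54, and -3.70 without HU_W 1 and -5.14 without HU_L 5. The 15 macrophage markers (mean -0.61, adjusted p = 6.82e-07) and 13 fibroblast and fibro-adipogenic progenitor markers (-0.29, adjusted p = 1.78e-05) were lower as lists, with 0 changed over all genes and 0 adjusted over the list alone; the adjusted p = 0.537 and 0.421 with an estimated correlation. DESeq2 called 2 genes, and 499 had an unadjusted p under 0.05. Liver transcripts stood out in HU_L 5 and in HU_W 1 and 2.

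With metformin and leucine during unloading (HU_ML), immediate early transcripts were lower. Of 12 immediate early genes 3 fell and 4 adjusted over the list alone (adjusted p = 7.03e-11, and 0.0093 with an estimated correlation). These were Fosb, 28.7-fold to 0.222 ± 0.0926 CPM, Fos, 9.95-fold to 2.84 ± 1.84 CPM, and Egr1, 4.63-fold to 6.08 ± 1.97 CPM (SD, n = 4; adjusted p = 0.00186, 0.0223 and 0.0179). Fosb passed without each of the 8 libraries, with a log2 fold change of -4.84, and -4.00 without HU_W 1 (adjusted p = 0.0458). Its call ended with voom, with only the 2 groups in the fit and without the 12 liver-transcript libraries. The 6 red blood cell transcripts had a mean log2 fold change of -1.87, with 0 lower over all genes and 4 adjusted over the list alone (adjusted p = 2.85e-08, and 0.0381 with an estimated correlation). The phosphatase gene Dupd1 rose 2.44-fold to 18.9 ± 8.56 CPM and Pan3, of a complex that shortens poly(A) tails, fell 1.42-fold. Ribosomal proteins were higher as a list (21 tested, mean 0.28, 0 over all genes and 8 adjusted over the list alone, adjusted p = 1.12e-09, adjusted p = 0.0982 with an estimated correlation). Interferon-stimulated genes were lower (13 tested, -0.71, 0 over all genes and 0 adjusted over the list alone, adjusted p = 0.000137, adjusted p = 0.594 with an estimated correlation).

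Satellite cells and matrix, the subject of the series title, were looked at in each ML group. In HU_ML, Pax7 stood at 1.74 ± 0.452 CPM against 1.66 ± 0.252 CPM with water (log2 fold change 0.08 ± 0.28 SE, n = 4, edgeR adjusted p = 0.977), and Col1a1 at 17.8 ± 3.12 CPM against 11.6 ± 4.13 CPM (0.62 ± 0.56, adjusted p = 0.898). Of 12 satellite cell markers and 22 matrix proteins 0 changed over all genes and 0 adjusted over the list alone (mean 0.13 and 0.14, adjusted p = 0.391 for both, adjusted p = 0.871 with an estimated correlation). In all, 8 genes changed in HU_ML, 2 up and 6 down. The count was 2 without HU_W 1 or HU_ML 1, 3 without HU_W 2 or HU_ML 5, 5 without HU_ML 6, 13 without HU_W 4, 17 without HU_ML 4 and 3 without the 12 liver-transcript libraries. The calls of Fos and Egr1 ended without HU_W 1, HU_ML 1 or HU_ML 5, that of Fos also without HU_W 2 or 3 (highest adjusted p = 0.235 and 0.217). Those of Dupd1 and Pan3 ended without HU_W 1, HU_W 2, HU_ML 1 or HU_ML 6, with HU_W 3 for Dupd1 and HU_ML 5 for Pan3 (0.449 and 0.306).

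At 7 d of reloading, metformin (RL7_M) was set against RL7_W. Ube2c, a ubiquitin-conjugating enzyme of mitosis, was 7.44-fold higher at 11.6 ± 5.02 CPM (SD, n = 4; log2 fold change 2.90 ± 0.41 SE, edgeR adjusted p = 4.06e-05), and Rabep2, an endosome protein, 6.56-fold higher at 23 ± 5.56 CPM (adjusted p = 3.65e-06). Both lie opposite to an abundant muscle gene, Ube2c to Tnnc2 and Rabep2 to Atp2a1, so which strand their counts came from is uncertain; the opposite-strand index averaged 0.29 ± 0.29 in RL7_M and -0.36 ± 0.09 in RL7_W. Of 11 mitochondrially encoded subunits 3 fell and 7 adjusted over the list alone (adjusted p = 2.11e-11, adjusted p = 0.222 with an estimated correlation), mt-Cytb 2.2-fold to 7580 ± 2430 CPM, and 5.8S rRNA fell 5.42-fold to 0.904 ± 0.537 CPM. The 10 adipocyte markers had a mean log2 fold change of 2.32, with 0 higher over all genes and 8 adjusted over the list alone (adjusted p = 4.06e-07, adjusted p = 0.222 with an estimated correlation). Without RL7_M 4 their mean was 0.21 and the adjusted p 0.966, and voom also ended the call.

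Of 22 matrix proteins 0 changed over all genes and 0 adjusted over the list alone in RL7_M (mean 0.33, adjusted p = 0.0156, adjusted p = 0.98 with an estimated correlation), and the call ended with voom and without RL7_W 3, RL7_W 4, RL7_M 3 or RL7_M 4 (highest adjusted p = 0.351). Pax7 had a log2 fold change of 0.65 ± 0.28 (n = 4, edgeR adjusted p = 0.303). In all 23 genes changed, 15 up and 8 down, and DESeq2 called 72. The count was 15, 14, 10 and 11 without RL7_W 1, 2, 3 and 4, was 78, 36, 47 and 11 without RL7_M 1, 2, 3 and 4, and was 192 without the 12 liver-transcript libraries. The calls of mt-Cytb and n-R5-8s1 ended without RL7_W 3, RL7_W 4 or RL7_M 4 (highest adjusted p = 0.199 and 0.105).

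Leucine at 7 d (RL7_L against RL7_W) gave 13 changed genes, 12 up and 1 down. The fit of only the groups compared gave 17 up and 23 down, and that without RL14_ML 1 and 6 gave 21 up and 25 down. The other settings kept more genes up than down. Ube2c was 8.97-fold higher at 13.9 ± 2.38 CPM (SD, n = 4; log2 fold change 3.17 ± 0.41 SE, edgeR adjusted p = 4.66e-06) and Rabep2 7.17-fold higher (adjusted p = 1.11e-06), with an opposite-strand index of 0.53 ± 0.07 in RL7_L. The 5.8S rRNA gene n-R5-8s1, the 1 gene that fell, was 6.52-fold lower at 0.771 ± 0.272 CPM. The 11 mitochondrially encoded subunits had a mean log2 fold change of -0.75, with 0 lower over all genes and 7 adjusted over the list alone (adjusted p = 2.07e-10, adjusted p = 0.346 with an estimated correlation). Matrix proteins were higher as a list (22 tested, mean 0.48, 0 over all genes and 0 adjusted over the list alone, adjusted p = 4.36e-05), and so were adipocyte markers (10 tested, mean 1.44, 0 and 0 adjusted over the list alone, adjusted p = 0.00062). Both had an adjusted p = 0.443 with an estimated correlation, the matrix mean was 0.318 without RL7_W 4, and the adipocyte call ended without the 12 liver-transcript libraries.

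Metformin with leucine at 7 d (RL7_ML against RL7_W) gave higher glycolysis and matrix lists. Of 14 glycolysis genes 0 changed over all genes and 11 rose adjusted over the list alone (mean log2 fold change 0.43 ± 0.16, SD over genes, adjusted p = 6.39e-12, adjusted p = 0.289 with an estimated correlation). Matrix proteins had a mean of 0.34 (22 tested, 0 over all genes and 0 adjusted over the list alone, adjusted p = 0.00574, adjusted p = 0.855 with an estimated correlation), and the list no longer passed without RL7_W 4 or RL7_ML 3 (highest 0.557). The 11 mitochondrially encoded subunits had a mean of -0.57, with 0 lower over all genes and 5 adjusted over the list alone (adjusted p = 3.54e-07, adjusted p = 0.527 with an estimated correlation), beside 1.76 ± 1.26 CPM of 5.8S rRNA. Pax7 stood at 2.22 ± 0.409 CPM against 1.63 ± 0.466 CPM (SD, n = 4; log2 fold change 0.45 ± 0.28 SE, edgeR adjusted p = 0.613) and Col1a1 at 58 ± 36.5 CPM against 33.8 ± 20.5 CPM (0.78 ± 0.54, adjusted p = 0.646). Satellite cell markers as a list had a mean of 0.10 (12 tested, 0 over all genes and 0 adjusted over the list alone, adjusted p = 0.352, adjusted p = 0.855 with an estimated correlation). The 1 gene that changed was A930016O22Rik, named after its value was seen because the rule leaves out such names. It lies opposite to Ckm, muscle creatine kinase, and was 5.17-fold higher at 5.27 ± 2.78 CPM (adjusted p = 0.000947). DESeq2 called 20 genes, voom 638, 3 were called without RL7_ML 4, and 1516 had an unadjusted p under 0.05.

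At 14 d of reloading, metformin (RL14_M) was set against RL14_W and 853 genes changed, 257 up and 596 down. Of 6 red blood cell transcripts 6 rose, and 6 adjusted over the list alone (adjusted p = 3.16e-08, and 0.035 with an estimated correlation), Hbb-bs 12.2-fold to 14.6 ± 14.3 CPM (SD, n = 4; log2 fold change 3.61 ± 0.65 SE, and 2.701 without RL14_M 6). Of 11 mitochondrially encoded subunits 9 rose and 11 adjusted over the list alone (adjusted p = 1.43e-15, and 0.035 with an estimated correlation), mt-Cytb 2.45-fold to 28800 ± 6880 CPM and mt-Co2 6.62-fold. Beside them n-R5-8s1 rose 24.9-fold (adjusted p = 8.79e-08), and all 4 RL14_W libraries held less 5.8S rRNA than any RL14_M library. With 5.8S rRNA as a covariate the mean log2 fold change of the mitochondrial list was 0.68 in place of 1.42, and 0 genes changed. Myod1, a master factor of muscle cell fate, fell 1.92-fold to 6.71 ± 2.13 CPM (adjusted p = 0.0422), and Cdh15, M-cadherin of satellite cells, 1.82-fold (adjusted p = 0.0128). Pax7 stood at 1.33 ± 0.326 CPM against 2.44 ± 0.0881 CPM (-0.88 ± 0.28, adjusted p = 0.0531, and from 0.00399 with voom to 0.999 with 5.8S rRNA as a covariate over its alternatives).

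Further lists moved with metformin at 14 d. Of 14 glycolysis genes 4 fell and 9 adjusted over the list alone (adjusted p = 2.48e-06, adjusted p = 0.37 with an estimated correlation), Aldoa, aldolase of muscle, by 1.56-fold and Pfkm, its phosphofructokinase, by 1.47-fold. Of 21 ribosomal proteins 8 fell and 12 adjusted over the list alone (adjusted p = 0.00402, adjusted p = 0.501 with an estimated correlation). Of 15 macrophage markers 1 rose, the scavenger receptor Cd163, by 2.09-fold, and 3 adjusted over the list alone (adjusted p = 3.88e-05, adjusted p = 0.389 with an estimated correlation). Of 12 satellite cell markers 1 fell and 2 adjusted over the list alone (mean -0.35, adjusted p = 0.0242, adjusted p = 0.385 with an estimated correlation). The satellite cell and glycolysis lists no longer passed with 5.8S rRNA as a covariate. Tfeb, which drives lysosome genes, fell 2.07-fold to 18.8 ± 3.5 CPM, Atf4 1.55-fold and Eif4ebp1 1.76-fold, and the fast myosin Myh1 rose 2.62-fold. The count of 853 was 266 without RL14_M 1, 362 without RL14_M 2 and 2292 without RL14_ML 1 and 6. It was 41 without RL14_W 3 (24 up, 17 down) and 64 without RL14_W 4 (35 up, 29 down). Without RL14_M 6 it was 72 (52 up, 20 down). The other settings that called any gene kept more down than up. Without RL14_M 6 each of the genes named here but Hbb-bs, mt-Cytb, mt-Co2 and n-R5-8s1 missed the threshold (highest adjusted p from 0.0564 for Atf4 to 0.171 for Myod1 over all libraries left out), as each but Atf4 did without RL14_W 3 or 4. Myod1 and Myh1 also missed it without RL14_W 5, RL14_M 1 or RL14_M 2, Cd163 without RL14_W 5, RL14_M 2 or RL14_M 5, Myod1 without RL14_W 1, and Tfeb and Eif4ebp1 without RL14_M 1.

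Leucine at 14 d (RL14_L against RL14_W) gave 49 changed genes, 34 up and 15 down. Of 11 mitochondrially encoded subunits 5 rose and 10 adjusted over the list alone (adjusted p = 9.97e-14, adjusted p = 0.11 with an estimated correlation), mt-Cytb 2.15-fold to 25200 ± 8200 CPM (SD, n = 4; log2 fold change 1.10 ± 0.23 SE, edgeR adjusted p = 0.0259). The mitochondrial ribosomal RNA mt-Rnr1 rose 6.15-fold and n-R5-8s1 25.7-fold. Gbp2, an interferon-response gene, rose 3.1-fold to 11.8 ± 10.9 CPM, and its call ended without RL14_L 2 or any of the 4 RL14_W libraries (highest adjusted p = 0.188). Gsn, gelsolin, which severs actin, fell 1.86-fold to 167 ± 62.5 CPM and Gstp2 2.02-fold. The 6 red blood cell transcripts had a mean of 2.13, with 0 higher over all genes and 4 adjusted over the list alone (adjusted p = 0.000615, adjusted p = 0.38 with an estimated correlation). The 21 ribosomal proteins had a mean of -0.20 (-0.132 without RL14_L 4), with 0 and 11 lower adjusted over the list alone (adjusted p = 0.0017, adjusted p = 0.509 with an estimated correlation). The 12 satellite cell markers had a mean of -0.36, with 0 and 1 lower adjusted over the list alone (adjusted p = 0.00705, adjusted p = 0.398 with an estimated correlation). With 5.8S rRNA as a covariate the satellite cell and mitochondrial lists no longer passed, nor did the ribosomal list with only the 2 groups in the fit. The count of 49 was 11, 5, 7 and 83 without RL14_W 1, 3, 4 and 5, was 86, 161, 17 and 24 without RL14_L 1, 2, 4 and 5. It was 17 without the 12 liver-transcript libraries, 2 with 5.8S rRNA as a covariate and 1112 (420 up, 692 down) without RL14_ML 1 and 6. Voom gave 455 up and 890 down, and the fit of only the groups compared 116 up and 118 down, while the other settings kept more genes up than down. The calls of mt-Cytb, Gsn and Gstp2 ended without RL14_W 1, RL14_W 3, RL14_W 4, RL14_L 4 or RL14_L 5 (highest 0.151, 0.2 and 0.171).

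Metformin with leucine at 14 d (RL14_ML against RL14_W) went with higher mitochondrial and ribosomal RNA. Of 11 mitochondrially encoded subunits 8 rose and 9 adjusted over the list alone (adjusted p = 2.83e-16, and 0.0459 with an estimated correlation), mt-Cytb 2.17-fold to 25400 ± 10600 CPM (SD, n = 4; log2 fold change 1.12 ± 0.24 SE, edgeR adjusted p = 0.0103). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 rose 8.61-fold and 10.7-fold (log2 fold change 3.11 and 3.42, and 2.38 and 2.50 without RL14_ML 6), and n-R5-8s1 32.9-fold. Of 21 ribosomal proteins 6 fell and 12 adjusted over the list alone (adjusted p = 2.25e-11, adjusted p = 0.0746 with an estimated correlation). Rps21, a ribosomal protein outside this list, fell 1.96-fold. Ppp1r3c fell 2.24-fold to 127 ± 31.4 CPM, Lrrc30 2.29-fold, the stress phosphatase subunit Ppp1r15a 1.92-fold and the clock gene Arntl 2.22-fold. The 6 red blood cell transcripts had 1 higher over all genes, Hbb-bs by 6.21-fold, and 4 adjusted over the list alone (adjusted p = 2.77e-05, adjusted p = 0.142 with an estimated correlation, and 0.0564 without RL14_ML 1). Glycolysis genes were lower as a list (14 tested, mean -0.32, and -0.517 without RL14_ML 1, 0 over all genes and 3 adjusted over the list alone, adjusted p = 8.47e-08, adjusted p = 0.233 with an estimated correlation). The mitochondrial, glycolysis and red blood cell lists no longer passed with 5.8S rRNA as a covariate, nor did the last with voom.

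Pax7 in RL14_ML stood at 2.43 ± 1.12 CPM against 2.44 ± 0.0881 CPM with water (log2 fold change 0.00 ± 0.27 SE, n = 4, edgeR adjusted p = 1) and Col1a1 at 42.8 ± 9.63 CPM against 45.9 ± 34.4 CPM (-0.10 ± 0.53, adjusted p = 0.969). Satellite cell markers (12 tested, mean -0.05, median -0.08, adjusted p = 0.375, adjusted p = 0.762 with an estimated correlation) and matrix proteins (22 tested, mean 0.06, median -0.01, adjusted p = 0.795, adjusted p = 0.93 with an estimated correlation) had 0 changed over all genes and 0 adjusted over the list alone. RL14_ML 1 had a mean log2 CPM of 2.89 over the satellite cell markers, against 2.02 to 2.20 in the other 3 libraries. Without it the list had a mean of -0.32 (adjusted p = 0.0839) and Pax7 a log2 fold change of -0.38; without RL14_ML 1 and 6 the list was lower with a mean of -0.39 (adjusted p = 0.03, the lowest over its alternatives, up to 0.907). Matrix proteins were higher without RL14_W 1 (mean 0.39, adjusted p = 0.0173, the lowest over their alternatives, up to 0.966). In all 119 genes changed, 62 up and 57 down. The count was 79, 30 and 29 without RL14_W 1, 3 and 4, was 2500, 72 and 64 without RL14_ML 1, 3 and 6, was 1176 without RL14_ML 1 and 6 together and 0 with 5.8S rRNA as a covariate. The calls of Arntl (highest adjusted p = 0.117), mt-Cytb (0.114), Rps21 (0.05) and Hbb-bs (0.188) ended without RL14_W 3. So did those of all but Rps21 without RL14_W 4, that of mt-Cytb without RL14_ML 6, those of Arntl and Hbb-bs without RL14_ML 3 and that of Hbb-bs without RL14_W 1, RL14_W 5 or RL14_ML 6.

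What the combination added to either compound was asked with ML against M and against L. Against HU_M, HU_ML had lower blood transcripts. Hbb-bs was 6.9-fold lower at 4.3 ± 2.31 CPM against 29.7 ± 31.4 CPM (SD, n = 4; log2 fold change -2.79 ± 0.58 SE, edgeR adjusted p = 0.0332), Egr1 4.43-fold and Fosb 20.4-fold. Of 6 red blood cell transcripts 3 fell and 6 adjusted over the list alone (adjusted p = 1.49e-09, and 0.0249 with an estimated correlation), with a mean of -2.50, and -1.29 (-1.295) without HU_M 3. Of 12 immediate early genes 2 fell and 5 adjusted over the list alone (mean -1.04, adjusted p = 8.37e-07, adjusted p = 0.104 with an estimated correlation). Glycolysis genes (14 tested, mean 0.40, 0 over all genes and 8 higher adjusted over the list alone, adjusted p = 4.42e-09) and ribosomal proteins (21 tested, mean 0.27, 0 and 11 higher adjusted over the list alone, adjusted p = 5.03e-07) were higher as lists, and had an adjusted p = 0.246 with an estimated correlation. In all 25 genes changed, 7 up and 18 down. The count was 0 without HU_ML 1, HU_ML 5 or HU_ML 6, 1 without HU_M 3, 39 without HU_M 4 and 51 without HU_ML 4. The calls of Hbb-bs (highest adjusted p = 0.417), Egr1 (0.13) and Fosb (0.112) ended without HU_ML 1, HU_ML 5 or HU_ML 6, and those of Hbb-bs and Egr1 without HU_M 3. The log2 fold change of Fosb was -4.35, and -3.35 without HU_M 1, and that of Hbb-bs -1.72 without HU_M 3.

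Against HU_L, 16 genes changed in HU_ML, 2 up and 14 down. The sialyltransferase gene St8sia6 was 2.13-fold lower at 2.81 ± 0.378 CPM (SD, n = 4; edgeR adjusted p = 0.0298), Mindy1, a deubiquitinase, 1.54-fold higher, and n-R5-8s1 4.15-fold lower. Ribosomal proteins were higher as a list (21 tested, mean 0.27, 0 over all genes and 10 adjusted over the list alone, adjusted p = 4.51e-07) and mitochondrially encoded subunits lower (11 tested, mean -0.67, 0 and 8 adjusted over the list alone, adjusted p = 4.37e-08). Both had an adjusted p = 0.426 with an estimated correlation. The count was 29, 8 and 8 without HU_L 1, 2 and 5, was 5, 30, 7 and 3 without HU_ML 1, 4, 5 and 6, and was 1 without the 12 liver-transcript libraries. The calls of St8sia6 and Mindy1 ended without HU_L 5, HU_ML 1, HU_ML 5 or HU_ML 6, with HU_L 1 for the first and HU_L 2 or HU_ML 4 for the other (highest adjusted p = 0.225 and 0.323). That of n-R5-8s1 ended without HU_L 5, HU_ML 5 or HU_ML 6 (0.163).

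At 7 d of reloading, the adipocyte markers were lower in RL7_ML than in RL7_M (10 tested, mean log2 fold change -1.85, 0 over all genes and 7 adjusted over the list alone, adjusted p = 6.38e-10, adjusted p = 0.0973 with an estimated correlation). Without RL7_M 4 their mean was 0.24, and voom ended the call. Immediate early genes were lower too (12 tested, mean -0.69, 0 over all genes and 3 adjusted over the list alone, adjusted p = 3.95e-06, adjusted p = 0.124 with an estimated correlation), and less so without RL7_M 3 (mean -0.314, adjusted p = 0.0391). With edgeR 0 genes changed, 634 had an unadjusted p under 0.05, DESeq2 called 0, voom 4, and 17 were called without the 12 liver-transcript libraries. Against RL7_L, respiratory chain subunits of the nucleus were higher (20 tested, mean 0.24, 0 over all genes and 0 adjusted over the list alone, adjusted p = 1.84e-08, adjusted p = 0.399 with an estimated correlation), with a mean of 0.158 without RL7_L 2 and 0.15 without RL7_ML 1. Proliferation genes were lower (11 tested, mean -0.86, 0 and 1 adjusted over the list alone, adjusted p = 2.24e-07, adjusted p = 0.108 with an estimated correlation, and 0.298 without RL7_L 5), and not without the 12 liver-transcript libraries. With edgeR 0 genes changed, 576 had an unadjusted p under 0.05, and DESeq2 called 3 and voom 4. Leaving out RL7_L 1, RL7_L 5, RL7_ML 1 or RL7_ML 3 gave 1, 4, 1 and 2.

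At 14 d, RL14_ML against RL14_M gave 4 genes, all higher: Vaultrc5, Gm23935, Gm15564 and CT010467.1, named after their values were seen. Gm23935 had 1830 ± 3470 CPM against 56.2 ± 8.01 CPM (SD, n = 4, edgeR adjusted p = 0.015). The ribosomal RNA gene CT010467.1 had 18600 ± 14900 CPM against 5560 ± 824 CPM (adjusted p = 0.0484). Without RL14_ML 1, which held 7026 CPM of Gm23935, 0 genes were called. The count was also 0 without RL14_M 1, 2 or 6, 1 without RL14_M 5, and 128, 17 and 146 without RL14_ML 3, 4 and 6. Pax7 had a log2 fold change of 0.88 ± 0.28 (adjusted p = 0.321). Macrophage markers (15 tested, mean -0.48, 0 over all genes and 0 adjusted over the list alone, adjusted p = 0.000744, adjusted p = 0.624 with an estimated correlation) and red blood cell transcripts (6 tested, mean -1.22, 0 and 0 adjusted over the list alone, adjusted p = 0.000744, adjusted p = 0.602 with an estimated correlation) were lower as lists. The first was lost without RL14_ML 6 (0.0727) and the other without RL14_M 6 (0.166). Against RL14_L, edgeR called 0 genes, 1174 had an unadjusted p under 0.05, DESeq2 called 24 and voom 0. 73, 70, 4, 10 and 6 were called without RL14_L 1, RL14_L 2, RL14_ML 3, RL14_ML 4 and RL14_ML 6. Ribosomal proteins were lower as a list (21 tested, mean -0.11, 0 and 0 adjusted over the list alone, adjusted p = 0.0127, adjusted p = 0.855 with an estimated correlation), and not without RL14_L 2, RL14_ML 1, RL14_ML 6 (highest 0.46) or both of the last; the mean was -0.178 without RL14_L 4.

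Whether the effect of a drink differed between unloading and the reloading times was tested with 6 interaction terms in edgeR. 155 of 16668 genes differed, and 2741 had an unadjusted p under 0.05. Mitochondrial genes were among them: mt-Cytb (F = 11.6, adjusted p = 0.000213), mt-Nd5 (F = 9.45, adjusted p = 0.000932) and mt-Co2 (F = 7.93, adjusted p = 0.00554) differed, as did n-R5-8s1 (F = 29.7, adjusted p = 2.21e-09). Atf4 (adjusted p = 0.0351), Egr1 (0.0377) and Hbb-bs (0.0256) differed too. Pax7 (F = 3.06, adjusted p = 0.18) and Col1a1 (F = 1, adjusted p = 0.716) did not pass.

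**Figure D3:**
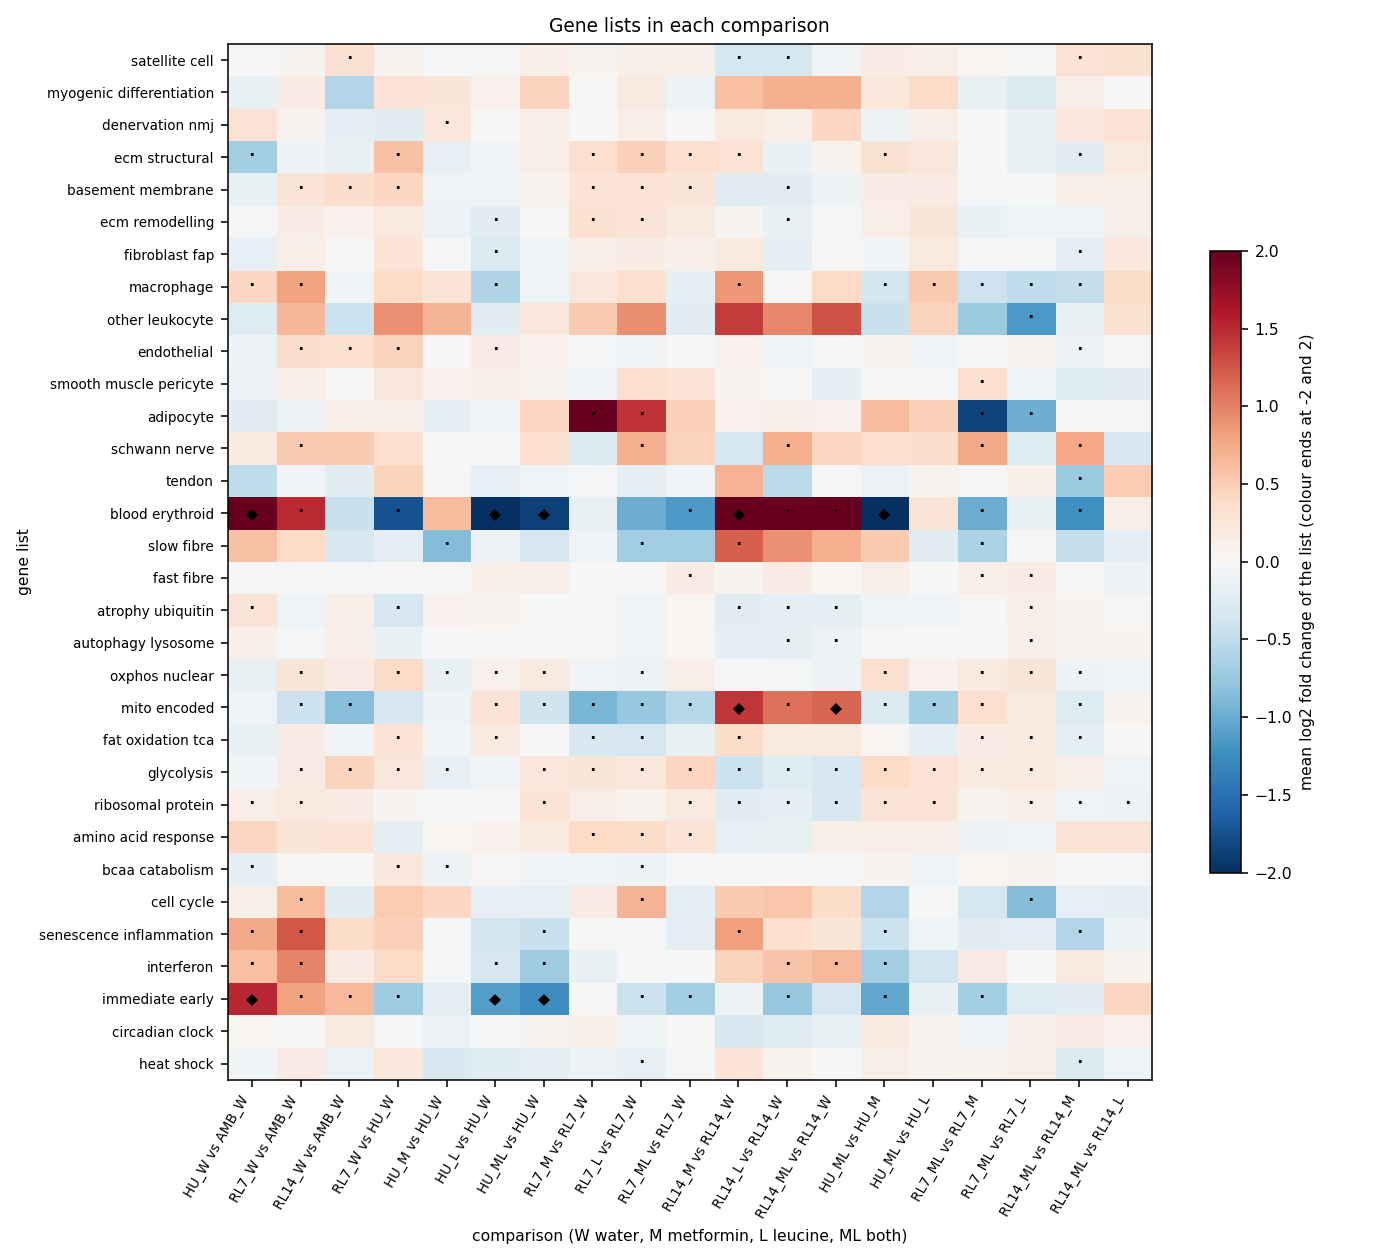
Mean log2 fold change of the 32 lists in the 19 comparisons, in colour; a dot marks an adjusted p under 0.05 with the preset correlation of 0.01 and a diamond one under 0.05 with the estimated correlation. The mitochondrially encoded list had a mean of 1.42, 1.10 and 1.17 in RL14_M, RL14_L and RL14_ML against water, and of -0.91, -0.75 and -0.57 in RL7_M, RL7_L and RL7_ML.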

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

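Tests chosen only after the result was seen were the share of genes opposite to an abundant gene, the range of the opposite-strand index, the level of nuclear respiratory chain genes and the covariate for 5.8S rRNA.

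At 7 d of reloading, 17 genes rose with metformin or leucine, and 13 of them (76.5%) lie opposite to an abundant gene, against 0.895% of 16642 genes tested (Fisher exact p = 3.21e-24). A candidate explanation, for which the values needed are there, is that reads from the strand of the abundant gene were counted for its neighbour, in amounts that differ between libraries. The spread at 7 d could not tell a library difference that follows no group from an effect of the drinks. The index ran over 0.625 within RL7_M, in no order of library numbers, which is 0.957 times the difference of 0.65 between RL7_M and RL7_W. The lowest RL7_L (0.43) and RL7_M (-0.04) libraries lay above the highest RL7_W library (-0.25), but the index averages genes of the class that holds 13 of the 17 called genes, so this gap restates the calls and excludes nothing. The 14 d libraries took no part in the choice of these 17 genes. There the highest RL14_W library had -0.193, and the lowest RL14_M, RL14_L and RL14_ML libraries had 0.163, -0.007 and -0.086. These values argue against a library difference that follows no group at 14 d. During unloading the index overlapped between drinks (-0.253 to -0.122 in HU_W and -0.349 to -0.068 in HU_M). Handling that follows the groups, and an effect of the drinks on transcription of the opposite strand, stayed open and were not tested.

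At 14 d, the mitochondrially encoded list was higher with each drink, beside more 5.8S rRNA, and less complete removal of ribosomal RNA may be the source. With 5.8S rRNA as a covariate, 47.7, 31.6 and 29.5% of the mean log2 fold change was left in RL14_M, RL14_L and RL14_ML (1.42 ± 0.56 to 0.68 ± 0.46, 1.10 ± 0.30 to 0.35 ± 0.32 and 1.17 ± 0.56 to 0.34 ± 0.35, SD over 11 genes). The list still passed in RL14_M and no longer in the others, where the means fell while the median SE rose from 0.27 to 0.50 and 0.53. The largest share left was under the bound for this explanation, but the list kept its call in RL14_M. The 5.8S rRNA follows the groups (up to 0.998 CPM in RL14_W, at least 9.15 CPM in treated libraries). A handling difference and an untested drink effect on mitochondrial transcription cannot be told apart. More mitochondria in the muscle would raise the nuclear respiratory chain list as well. Its median in RL14_M was 0.023 ± 0.276 (SD, 20 genes), where 0.64 was needed, so this list argues against it in RL14_M. Nuclear genes of fat oxidation and the citric acid cycle were higher there as a list (21 tested, median 0.287 ± 0.511, SD over genes). That list had a cameraPR adjusted p = 0.0145, and 0.686 with an estimated correlation, so the question was not settled. RL14_L and RL14_ML were not examined this way.

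During unloading, the 6 red blood cell transcripts were lower in HU_L and HU_ML than in HU_W (mean log2 fold change -2.12 and -1.87), and less blood in the muscle piece may be the source. Markers of neutrophils, fixed as a list of 7, had a median of -0.03 in HU_L and 0.03 (0.028) in HU_ML, which met the bound set beforehand against this explanation. That bound was wrong because 2 of the 7 were tested (Lcn2 near 0.939 and S100a9 near 0.11 CPM in HU_W), too few and too near the floor to decide. Platelet markers, 6 of 7 tested, went the other way, with medians of -3.69 ± 1.53 and -2.92 ± 1.73 (SD over genes), and no bound was set for them beforehand. Ppbp, the most abundant of them, stood at 3.59 ± 2.91 CPM in HU_W, 0.308 ± 0.243 in HU_L and 0.217 ± 0.134 in HU_ML (SD, n = 4). The others stood between 0.528 ± 0.421 (Gp6) and 1.36 ± 0.724 CPM (Pf4) in HU_W, also near the floor. Pf4 stood at 1 ± 0.367 CPM in HU_ML, so platelet markers do not decide the question either. Less blood at dissection and fewer circulating or young red cells cannot be told apart, and no biological explanation was tested.

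In 21 of 459 tested sets of 4 libraries, 1 library lay far from the other 3 (its gap to the nearest as a share of the range is given in brackets). Chance flags about 1 in 20 groups, or 23 of these. Mitochondrial genes took 5.88% of counts in RL7_L 5 against 9.15 to 9.42% (0.924). The log2 CPM of 5.8S rRNA was 5.04 in HU_L 5 against 3.85 to 4.02 (0.86, as a library measure and as the gene n-R5-8s1). List means on the log2 scale stood apart for mitochondrially encoded subunits in RL7_M 4 (9.11 against 9.99 to 10.08, 0.905), matrix proteins in RL7_ML 3 (5.62 against 4.83 to 4.95, 0.843), glycolysis in HU_ML 1 (9.95 against 9.69 to 9.72, 0.868) and heat shock genes in HU_W 3 (5.61 against 4.66 to 4.82, 0.837). Higher than the rest on the log2 CPM scale were Aplnr in AMB_W 4 (1.62 against 0.64 to 0.78, 0.854), and Nr1d1 in AMB_W 2 (7.61 against 7.27 to 7.32, 0.85). The same held for Pgam2 in HU_W 1 (8.82 against 8.22 to 8.30, 0.866), Hbb-bt in RL14_W 5 (-1.86 against -3.30, 1), and Acadl in RL14_W 1 (7.52 against 6.64 to 6.78, 0.842). So was Gbp2 in RL14_L 2 (4.82 against 2.58 to 2.83, 0.889). Lower were Cldn5 in RL14_W 3 (1.35 against 2.01 to 2.10, 0.886), Col4a2 in HU_W 2 (5.00 against 5.38 to 5.42, 0.919), mt-Cytb in RL7_M 4 (11.96 against 13.02 to 13.17, 0.877), Cdh15 in RL14_M 6 (2.12 against 2.83 to 2.97, 0.84), and Pfkm in RL14_M 6 (10.44 against 10.66 to 10.69, 0.896). So were mt-Rnr1 in RL14_L 2 (13.77 against 14.83 to 14.90, 0.939), Mindy1 in HU_L 5 (3.54 against 4.14 to 4.20, 0.911) and Gm23935 in RL14_M 6 (5.47 against 5.89 to 5.94, 0.897).

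The fold change between a drink and water differed between times, by the test of 6 interaction terms in edgeR (adjusted p in brackets), for 25 of 113 named genes. Among mitochondrial and ribosomal RNA these were n-R5-8s1 (2.21e-09), mt-Rnr1 (3.56e-07), mt-Rnr2 (8.79e-06), mt-Cytb (0.000213), mt-Nd2 (0.000239), mt-Nd5 (0.000932), mt-Co2 (0.00554) and mt-Nd4l (0.00959). Genes that lie opposite to an abundant gene or code for small RNA included A930016O22Rik (0.000213), Rabep2 (0.0021), Ube2c (0.00462), Scarna10 (0.000439), Vaultrc5 (0.0286) and Mir6236 (0.0351). The rest were Haghl (0.00548), Rps21 (0.00913), Rpl8 (0.0161), Mindy1 (0.0243), Hbb-bs (0.0256), Hbb-bt (0.0269), Gstp2 (0.0325), Atf4 (0.0351), Egr1 (0.0377), Nr1d1 (0.0479) and Lrrc30 (0.0487).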

How the results depend on the processing

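Settings chosen after the data were seen were the covariate for 5.8S rRNA, the fit without 12 liver-transcript libraries and the fit without RL14_ML 1 and 6; the others were planned.

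Of 163 named gene results past the threshold, 60 stayed past it in the same direction with each library left out in turn and 32 did so under each of the other settings too. Among these 32 were Ddit4, Foxo1, Cebpd, Nfkbia and Aurka in HU_W against AMB_W, Ddit4, Foxo1, Foxo3, Ppp1r3c and Aplnr in RL7_W against HU_W, and Ube2c and Rabep2 in RL7_M and RL7_L against water. Of 72 list results past it 54 and 9 did. The 9 were red blood cell transcripts in HU_W against AMB_W, HU_L, HU_ML and RL14_M against water and HU_ML against HU_M, immediate early genes in HU_W against AMB_W and in HU_L and HU_ML against water, and the mitochondrially encoded list in RL14_M against water. The estimated correlation ended the call of 62 of these 72 list results, since a higher correlation widens the test. Of 180 gene results, 163 were past the threshold. Among these the call ended for 84 with the covariate, 83 without the liver-transcript libraries, 76 with no filter (36274 genes tested in place of 16668), and 45 with the groups compared alone. It ended for 12 with voom, 7 without RL14_ML 1 and 6, 4 with RLE and 0 with DESeq2, which brought 2 of the other results past the threshold.

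Counts of changed genes stayed within 1.5 times the value in the report in all 19 comparisons with RLE factors. Without a filter they were 2 (RL14_W against AMB_W), 458 (RL7_W against HU_W), 0 (HU_L against water), 2 (HU_ML), 12 (RL7_M), 195 (RL14_M), 19 (RL14_L), 59 (RL14_ML), 0 (HU_ML against HU_M), 3 (HU_ML against HU_L) and 1 (RL14_ML against RL14_M). With the covariate they were 0, 471 and 0 in the first 3 of these, 7 (RL7_M), 3 (RL7_ML), 0 (RL14_M), 2 (RL14_L), 0 (RL14_ML), 3 (HU_ML against HU_M) and 0 (HU_ML against HU_L). Without the liver-transcript libraries, which leaves 40, they were 123 (HU_W against AMB_W), 81 (RL14_W against AMB_W), 248 (RL7_W against HU_W), 0 (HU_L), 3 (HU_ML), 192 (RL7_M), 547 (RL14_M) and 17 (RL14_L). Between treated groups they were 47 (HU_ML against HU_M), 1 (HU_ML against HU_L), 17 (RL7_ML against RL7_M), 3 (RL7_ML against RL7_L), 0 (RL14_ML against RL14_M) and 1 (RL14_ML against RL14_L). Without RL14_ML 1 and 6 they were 1409 (RL14_W against AMB_W), 1355 (RL7_W against HU_W), 635 (RL7_M), 46 (RL7_L), 108 (RL7_ML), 2292 (RL14_M), 1112 (RL14_L), 1176 (RL14_ML), 102 (HU_ML against HU_M), 67 (HU_ML against HU_L) and 0 (RL14_ML against RL14_M). Apart from the larger number of genes with no filter and the fewer libraries, the cause was not tested.

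With only the groups compared in the fit, counts were 1050 (HU_W against AMB_W), 260 (RL7_W against AMB_W), 2029 (RL14_W against AMB_W), 2033 (RL7_W against HU_W), 3 (HU_L), 5 (HU_ML), 7 (RL7_M), 40 (RL7_L), 433 (RL7_ML), 2188 (RL14_M), 234 (RL14_L), 2 (RL14_ML), 0 (HU_ML against HU_M), 3 (HU_ML against HU_L) and 0 (RL14_ML against RL14_M). Voom with quality weights called 1362, 156, 2959 and 2743 in the 4 comparisons of water groups, 0 (HU_L), 55 (HU_ML), 444 (RL7_M), 144 (RL7_L), 638 (RL7_ML), 3896 (RL14_M), 1345 (RL14_L), 3021 (RL14_ML), 124 (HU_ML against HU_M), 125 (HU_ML against HU_L), 4 (RL7_ML against RL7_M), 4 (RL7_ML against RL7_L) and 1 (RL14_ML against RL14_M). DESeq2 called 20 (RL7_W against AMB_W), 288 (RL14_W against AMB_W), 16 (HU_M), 2 (HU_L), 28 (HU_ML), 72 (RL7_M), 40 (RL7_L), 20 (RL7_ML), 1328 (RL14_M), 187 (RL14_L), 208 (RL14_ML), 97 (HU_ML against HU_M), 76 (HU_ML against HU_L), 3 (RL7_ML against RL7_L) and 24 (RL14_ML against RL14_L). The cause was not tested.

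The replicate numbers did not pair the libraries: deviations from the group mean correlated by 0.0107 on average between libraries with the same number and -0.00225 otherwise, and 11 of 52 libraries had their best match under their own number. A replicate block gave 13 genes (RL14_W against AMB_W), 13 (HU_ML), 15 (RL7_M), 2 (RL7_ML), 431 (RL14_M), 47 (RL14_ML), 59 (HU_ML against HU_M) and 0 (RL14_ML against RL14_M). It turned Pax7 in HU_ML from 0.08 to -0.003 and in RL14_ML from -0.001 to 0.018. The cause was not tested.

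With 1 library left out, and so fewer samples, counts ran from 255 to 369 (HU_W against AMB_W), 1 to 69 (RL14_W against AMB_W), 408 to 796 (RL7_W against HU_W), 0 to 1 (HU_M and HU_L), and 2 to 17 (HU_ML). They ran from 10 to 78 (RL7_M), 1 to 3 (RL7_ML), 41 to 955 (RL14_M), 5 to 161 (RL14_L), and 29 to 2500 (RL14_ML). For the combination against either compound they ran from 0 to 51 (HU_ML against HU_M), 3 to 30 (HU_ML against HU_L), 0 to 4 (RL7_ML against RL7_L), 0 to 146 (RL14_ML against RL14_M) and 0 to 73 (RL14_ML against RL14_L). Counts peaked without HU_W 4 (HU_W against AMB_W, 369), HU_W 1 (RL7_W against HU_W, 796), RL14_W 5 (RL14_M, 955) and RL14_ML 1 (RL14_ML, 2500). Libraries that moved a count by over 1.5 times are named in the report.

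Reversed lists and named genes lay near 0 or rested on few libraries or on the covariate, and the cause was not tested. Gene calls turned mostly lower in RL7_M without RL14_ML 1 and 6, and mostly higher in HU_ML against HU_M with voom or a replicate block. The clock list in RL7_W against HU_W kept a mean of -0.043 (-0.072 to -0.03 with 1 library left out) and changed its direction in the rank of its genes with only the groups compared and without RL7_W 2. Adipocyte markers in RL7_ML against RL7_M went from -1.85 to -0.05 with voom, and from -2.20 to 0.24 with 1 library left out, 0.24 without RL7_M 4. Matrix proteins in RL14_ML ran from -0.16 to 0.39, with -0.05 without RL14_W 3 or 4 and -0.16 without RL14_ML 3. The covariate gave 0.19 for satellite cell markers in RL14_ML, 0.15 for mt-Rnr1 and -0.29 for Pax7 in RL14_W against AMB_W, 0.03 (0.025) for Myod1 in RL14_M, 0.02 (0.015) for Trim63 in RL7_W against AMB_W and -0.092 for Pax7 in HU_ML. It gave 0.61 (0.605) for Pax7 and 0.26 for Col1a1 in RL14_ML. Pax7 in HU_ML was also -0.06 (-0.055) without the liver-transcript libraries, -0.01 (-0.007) with voom and -0.05 (-0.046) to 0.22 with 1 library left out. Pax7 in RL14_ML was 0.00 (0.004) with RLE, 0.00 (0.002) with no filter and with only the groups compared, 0.01 (0.006) with DESeq2, and -0.38 to 0.11 with 1 library left out. Col1a1 ran from -0.83 to 0.048 in RL14_W against AMB_W and from -0.32 to 0.56 in RL14_ML with 1 library left out, and was 0.03 (0.026) without RL14_ML 1 and 6 and 0.31 with voom in RL14_ML.

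With 4 libraries per group at this depth, 34.3% of simulated 1.5-fold changes were recovered in HU_W against AMB_W and 26.9% in RL14_ML against RL14_W, so a missing call for a change of that size carries little information.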

Other observations

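The clock genes Per1, Dbp and Nr1d1 and the chaperones Hsph1 and Hspa8 passed in HU_W against AMB_W and in RL7_W against HU_W, while the clock list did not pass in either comparison. The list test asks for a shared direction, and clock genes moved both ways (SD over genes 0.632 and 0.667). It therefore cannot decide whether the clock genes changed as a set. The 2 comparisons share the HU_W libraries with opposite sign, so opposite directions are expected in part without any change, and no value for that part was computed. In HU_W against AMB_W, 1 of 13 clock genes rose and 2 fell, over all genes tested and over the list alone (mean log2 fold change 0.04, adjusted p = 0.669, adjusted p = 0.85 with an estimated correlation). Per1 was 2.7-fold higher at 153 ± 18.1 CPM against 56.6 ± 8.64 CPM (SD, n = 4; edgeR adjusted p = 0.00221). Dbp was 2.12-fold lower at 28 ± 5.2 CPM against 59.2 ± 4.38 CPM (0.000752) and Nr1d1 1.62-fold lower (0.0241; the call ended without AMB_W 2, HU_W 1 or HU_W 2, highest 0.102). In RL7_W against HU_W, 2 of 13 rose and 2 fell, and 3 and 3 over the list alone (mean -0.04, adjusted p = 0.914, adjusted p = 0.956 with an estimated correlation). Dbp rose 2.49-fold to 69.8 ± 2.41 CPM (3.45e-05) and Nr1d1 1.73-fold (0.00574), while Per1 fell 2.39-fold to 63.9 ± 20 CPM (0.00574) and Arntl 1.82-fold (0.045; the call ended without HU_W 2, 3 or 4 or RL7_W 2, 3 or 4, highest 0.13). The labels give no time of day for tissue collection.

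Hsph1, a chaperone of the heat shock response, was 1.86-fold lower in HU_W than in AMB_W at 32.7 ± 4.33 CPM against 60.8 ± 4.46 CPM (SD, n = 4; edgeR adjusted p = 0.000215). Hspa8, the constitutive chaperone of the Hsp70 family, was 1.43-fold lower (0.0439; the call ended without any library but HU_W 3, highest 0.182). Of 11 heat shock genes 2 fell and 0 rose, over all genes and over the list alone (mean log2 fold change -0.05, adjusted p = 0.15, adjusted p = 0.85 with an estimated correlation). In RL7_W against HU_W 2 rose and 0 fell, both ways (mean 0.22, adjusted p = 0.0508, adjusted p = 0.562 with an estimated correlation), Hsph1 2.05-fold to 67.1 ± 8.14 CPM (1.78e-05) and Hspa8 1.55-fold to 754 ± 70.4 CPM (0.00608). The list moved with HU_W 3: without it the mean was -0.37 against AMB_W (adjusted p = 0.00126, the lowest over the alternatives, up to 0.917 without the liver-transcript libraries, a setting chosen after the data were seen) and 0.53 in RL7_W against HU_W (0.000208, up to 0.562), where the list also passed without RL7_W 2 (0.0323) or RL7_W 3 (0.0477), with the replicate block (0.0368), with only the groups compared (0.0492) and, in settings chosen after the data were seen, with the 5.8S covariate (0.00403) and without RL14_ML 1 and 6 (0.0152). It passed with no filter, voom and DESeq2 in both comparisons.

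For each comparison the 8 libraries were split into 4 and 4 in all 35 ways, to see whether chance can be excluded as the source of its count of changed genes; the value after the slash is the highest of the other splits. The bound set beforehand against chance was met where the real split alone (1 of 35) gave as many genes. This was so for HU_W against AMB_W (464 / 0), RL14_W against AMB_W (29 / 0), and RL7_W against HU_W (813 / 1). The same holds for HU_ML (8 / 3), RL7_M (23 / 1), RL7_L (13 / 3) and RL14_M (853 / 303) against water and HU_ML against HU_L (16 / 12). That share is the smallest these splits can give, and it was not adjusted over the 19 comparisons, so it does not by itself exclude chance in any of them. The count of HU_ML falls to 2 without HU_W 1 or HU_ML 1, and that of HU_ML against HU_L to 3 without HU_ML 6. HU_L and RL7_ML against water (1 / 0 each) reach it too but rest on 1 gene, and the count of HU_L is 0 without HU_W 1, HU_L 1, HU_L 2 or HU_L 3, so chance is not taken as excluded for these either. The bound was missed, and chance cannot be excluded, for RL14_L against water (49 / 199, 6 of 35 splits gave as many), RL14_ML against water (119 / 4126, 8 splits), HU_ML against HU_M (25 / 25, 2 splits) and RL14_ML against RL14_M (4 / 804, 15 splits). For the 5 comparisons with a count of 0 by edgeR all 35 splits gave as many, the highest of the others being 0 (RL7_W against AMB_W), 1 (HU_M against HU_W), 1 (RL7_ML against RL7_M), 2 (RL7_ML against RL7_L) and 2134 (RL14_ML against RL14_L). In that order 1341, 647, 634, 576 and 1174 genes had an unadjusted p under 0.05, DESeq2 called 20, 16, 0, 3 and 24 and voom 156, 0, 4, 4 and 0. Splits of the 14 d libraries that call several times the real count point to a structure of these samples. The highest such splits against water differ from the real split by 1 exchange, of RL14_W 5 with RL14_L 2 or with RL14_ML 1, and without RL14_ML 1 the real count of RL14_ML is 2500.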
